A study of Arabidopsis thaliana with 12 samples.

How the data were processed

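The series measured RNA from seedlings of 4 Arabidopsis genotypes, 12 samples in all, on Affymetrix ATH1 arrays, 1 sample per array. Per the labels' protocols, the seedlings grew without treatment on Murashige and Skoog medium with Gamborg B5 vitamins at 23 °C and a light intensity of 100 µE. Total RNA, between 652 and 894 ng per array, was amplified and labelled with biotin, and 5.5 µg of single-stranded DNA is given for the labelling. The mean amount of RNA was 871 ng in SAB, against 751 in COL, 739 in AB and 727 in SIZ1, so it differed with genotype. The labels of AB 1 and AB 2 give an age of 10 days where the labels of the other samples give a harvest date, which is 1 and the same for all of those.

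The deposited values are log2 expression values per probe set, made by the authors with GCRMA, per the submitters' processing notes. GCRMA corrects the background of each probe by its sequence, normalizes between arrays and summarises the probes of a set. Its version, and whether all 12 arrays went through it together, is not given in the sources used here. That the values are on the log2 scale was read from their range, 2.02 to 13.21. GCRMA draws dim probe sets to a common floor, so the change of a transcript near the floor is understated, and the first quartile of the means was 2.51. The deposited values were used as they stand. The 64 control probe sets were left out of the tests, which left 22746.

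Probe sets were named from the platform's annotation table, with symbols updated through a RefSeq gene table of the assembly TAIR10.1. Exactly 1 gene was named for 13513 probe sets, of which 13436 had their symbol updated, several for 503, and 8730 are unnamed here. The 13513 name 13286 loci, and for 11751 of these the symbol is the locus code alone. No coordinates are printed, because no source gives the build used for the array's design.

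Differences were tested with limma 3.58.1 in R 4.3.3. A linear model with 1 term per genotype was fitted to all 12 arrays (lmFit and eBayes), so that the genotypes shared 1 estimate of the spread per probe set, with 8 residual and 1.31 prior degrees of freedom. The comparisons were AB, SIZ1 and SAB against COL, SAB against SIZ1, SAB against AB, and the departure of SAB from the sum of the changes in SIZ1 and AB. Tests were two-sided, and a probe set was called at a Benjamini-Hochberg adjusted p under 0.05. Positive values mean higher in the genotype named first. SE is limma's moderated standard error.

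Gene lists were tested with limma's camera with a preset correlation of 0.01, using for each locus the probe set with the highest mean over all arrays, with Benjamini-Hochberg adjustment over the lists of a comparison. Of 24 lists fixed before the data were examined, with 410 loci, 56 loci were measured under a name, and the 10 lists with at least 3 measured members were tested. A locus or member is called measured here only if a probe set names it alone. Others may be among the 8730 unnamed probe sets. The lists kept a smaller share of their loci than the array as a whole, where 13513 of 22746 probe sets name 1 gene. Camera was run again with the correlation estimated from the data. The call of the SUMO pathway in AB held then, and no other call of a fixed or added list against COL or of a fixed list in the other comparisons did. Lists with fewer measured members are reported only by their members. The plastid genome, a list of seed reserve loci, and the families formed by symbols that share a stem and hold at least 8 measured loci were added after the data were seen, 30 lists in all, and adjusted among themselves.

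The genes named in the text were chosen by a rule fixed before the data were examined. For each line against COL these were the 8 largest rises and 8 largest falls among called probe sets that name 1 gene and whose 3 values all lay on one side of the 3 COL values, leaving out those below the overall median in both groups. For the other comparisons 4 and 4 were taken by the same rule, without the condition on sides for the departure from the sum. SIZ1, the SUMO proteases SPF1, SPF2, OTS1, OTS2, ESD4, ULP1A and ULP1B, and up to 4 called members of each list were also to be named. OTS1, OTS2, ESD4 and ULP1A have no probe set that names them alone here and are left out. SPF2 and ULP1B are described with the SUMO pathway and not repeated for each comparison. Other genes and probe sets named in the text were chosen after their values were seen: unnamed probe sets, those near a threshold, members of the added lists, and the uncalled members of lists.

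Whether the replicate numbers pair the samples was checked before the fits were compared. The numbers are those in the sample names. Deviations from the genotype means correlated at 0.102 to 0.451 in all 18 pairs of arrays with the same number, with a median of 0.257, against a median of -0.125 in the 36 pairs with different numbers, and each of the 12 arrays was best matched by one with its own number. Deviations cancel out within each genotype, so the negative median follows from the positive one and is no separate evidence. From the same-number pairs and the best matches, the numbers were taken to pair the samples. The main fit stayed as fixed beforehand, without a block, so its counts and p-values ignore the pairing. Values from the fit with the number as a block are printed where they change a call or move a count by more than 1.5 times.

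The comparisons against COL share its arrays, so overlaps and correlations between them were set beside 100 simulations of unchanged groups. The correlations of SAB minus SIZ1 with AB minus COL, and of SAB minus AB with SIZ1 minus COL, share no array. The alternatives tried were quantile normalization, median centring, a filter on dim probe sets, only probe sets that name 1 gene, the replicate block, a trend and robust moderation, array quality weights, a fit to only the groups compared, a threshold of 2-fold, and each array left out in turn. A fit without SAB 3 and SIZ1 3 together was added after the data were seen, because their hybridization controls stood apart. Median centring changed the split of the calls between AB and COL from 4 higher and 10 lower to 7 and 7.

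The fits were tested on simulated data, with 200 of 22746 probe sets changed by known amounts, drawn from those above the overall median. With fewer true changes the adjusted threshold is stricter, so the shares called would be lower. For SIZ1 against COL, 41.8% of the probe sets changed by 0.5 on the log2 scale, 86.6% of those changed by 1 and 98.5% of those changed by 2 were called, with 13 false calls. For AB against COL the shares were 35.8%, 86.6% and 98.5%, with 6 false calls. With 1 list of the SIZ1 comparison shifted by 1, camera called it in each of 100 draws, and called 9 of 900 unshifted lists. The simulated loci were independent, so this does not test lists whose members correlate. The estimated correlation was 0.526 for the photosynthesis list and 0.635 for the salicylic acid list. It was -0.141 for the heat shock list and -0.0124 for the SUMO pathway, below the preset value.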

Results

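Transcript levels were measured in untreated Arabidopsis seedlings of 4 genotypes with the ATH1 expression array, 3 arrays per genotype and 12 in all. COL is the wild type, and AB, SIZ1 and SAB are the names the labels give to 3 knock-out lines made by T-DNA insertion. SIZ1 is the name of an E3 ligase that attaches the small protein modifier SUMO to other proteins. The labels do not say what AB and SAB stand for. The stated purpose of the series was to learn how ubiquitin-like proteases, the enzymes that process SUMO or remove it from its targets, influence transcription, and which transcripts change in the mutants. Values are on the log2 scale, ran from 2.02 to 13.21, and had a median of 3.51 over the means of the 22746 probe sets tested. The number of arrays limits the precision. Nothing in the labels says that the 3 samples of a genotype came from separate cultures, so the p-values measure the spread between these samples, which may be technical in part.

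The transcripts of the SUMO pathway were examined first, because they check the labels. The probe set with the higher SIZ1 signal in COL fell by 3.10 in the SIZ1 line, from 5.50 ± 0.12 (SD, n = 3) in COL to 2.40 ± 0.18, and by 2.98 in SAB, to 2.52 ± 0.03 (limma adjusted p = 3.99e-06 and 5.61e-06). In AB it stood at 5.26 ± 0.16, a difference from COL of -0.23 that was not called. Another SIZ1 probe set rose by 1.31 in the SIZ1 line and by 0.90 in SAB, from 3.01 ± 0.09 in COL (limma adjusted p = 0.00104 and 0.00565). The positions of the insertion and of the probes are not used here, so it is not known whether either probe set lies outside the part of the transcript that was disrupted. AT1G09730 (SPF1), a SUMO protease, fell by 1.59 in AB and by 1.53 in SAB, from 4.76 ± 0.03 in COL to 3.17 ± 0.33 and 3.23 ± 0.09 (limma adjusted p = 0.00633 and 0.000848). It stood at 4.29 ± 0.07 in SIZ1, a difference from COL of -0.48 that was not called (limma adjusted p = 0.0989). AT4G33620 (SPF2), a related protease, lay near the floor of the array in every genotype, from 2.63 to 2.77, so its level checks nothing. ULP1B, another SUMO protease, lay between 2.52 and 2.55. The proteases OTS1, OTS2, ESD4 and ULP1A have no probe set that names them alone here, so their levels were not checked. SAB therefore had low signal for both transcripts that were low in SIZ1 or in AB.

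**Figure D1:**
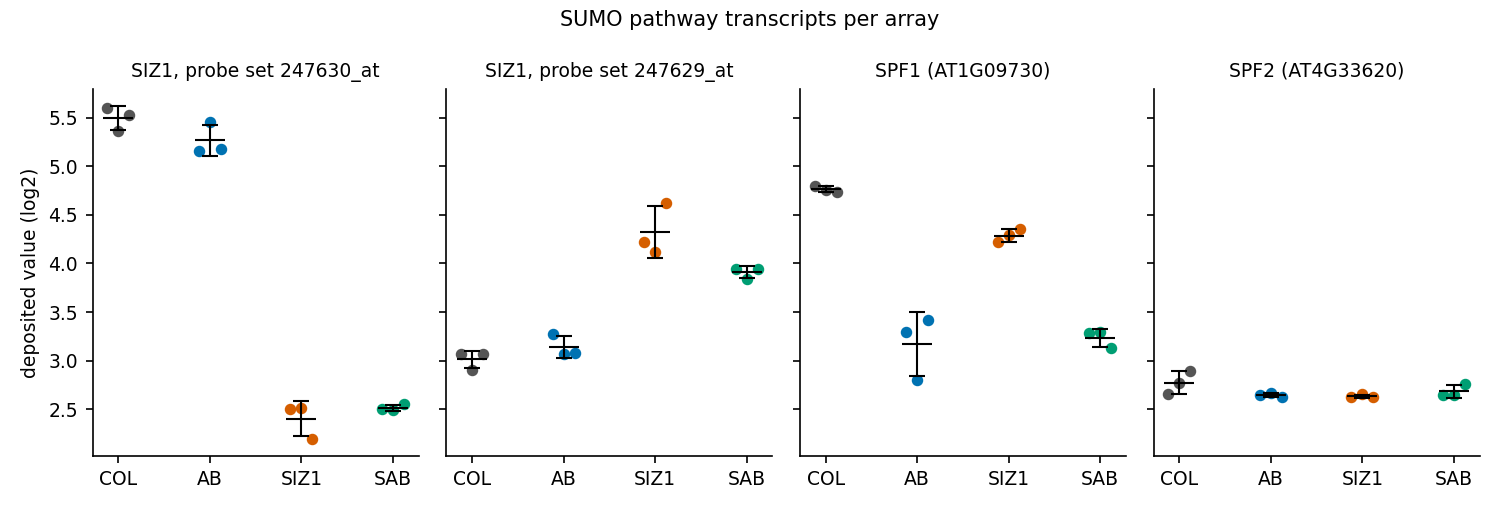
Deposited log2 values (y axis) of 4 probe sets for the SUMO pathway in each of the 12 arrays, by genotype (x axis). Points are arrays and bars are the mean and SD of 3; the SIZ1 probe set with the higher signal in COL is low in SIZ1 (2.40) and SAB (2.52), and SPF1 is low in AB (3.17) and SAB (3.23).

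AB and COL were compared to find the transcripts that change in the AB line. Few changed: 4 probe sets were higher and 10 lower (limma, adjusted p under 0.05), and 5 of these 14 name exactly 1 gene. AT4G07820, of the family of PR-1-like secreted proteins, rose by 1.22, from 7.16 ± 0.18 (SD, n = 3) to 8.38 ± 0.11 (limma adjusted p = 0.0181). AT1G33790, a jacalin-type lectin, rose by 1.01, from 3.06 ± 0.18 to 4.07 ± 0.20 (limma adjusted p = 0.0197). SPF1 had the largest fall among named genes, and smaller falls were found for AT1G11850 (-0.61, SE 0.08) and for AT1G07650, a receptor-like kinase with leucine-rich repeats (-0.43, SE 0.04). A pair of probe sets that are unnamed here changed by -1.61 and -1.51, close to the change of SPF1.

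Of the 24 gene lists fixed before the data were examined, 10 had at least 3 measured members. The SUMO pathway list was lower in AB (camera adjusted p = 0.000636, and 0.0344 with an estimated correlation). Of its 6 measured members only SPF1 was called, over all probe sets and adjusted over the list alone. The other 5 changed by -0.23 to -0.0042, so the call rests largely on SPF1, and the list was not tested without it. The heat shock list was higher (camera adjusted p = 0.0180), with a median change of 0.31. None of its 4 members was called over all probe sets, and 2 were higher when adjusted over the list alone. AT2G29500 (HSP17.6B), a small heat shock protein, stood at 3.57 in COL and 4.16 in AB, and AT5G48570 (ROF2) at 2.99 and 3.56. This call ended with an estimated correlation (adjusted p = 0.0914), with the replicate number as a block (adjusted p = 0.0523) and without AB 2 (0.0531). The correlation estimated for this list was -0.141, below the preset 0.01, so correlated members do not account for the first of these. Without AB 1 the salicylic acid and photosynthesis lists were called too (camera adjusted p = 0.0298 for each), and without SIZ1 3, whose array adds to the shared spread, the root markers (0.0313). The other 8 lists (salicylic acid defence, cold, flowering time, auxin, photosynthesis, flavonoids, root markers and reference genes) had camera adjusted p from 0.146 to 0.822, and the mean of the cold list differed in sign from its median and its test. The plastid genome, a list added after the data were seen, had a median of 0.06 and no called member (camera adjusted p = 0.0199, and adjusted p = 0.861 with an estimated correlation). The poly-A control probe sets, which detect RNA added during labelling, averaged 0.21 in AB relative to COL. With the replicate number as a block 74 probe sets were called, 28 higher and 46 lower. The count was 7 without COL 1, 27 without COL 3 and 24 without AB 2, the call of AT1G11850 ended without any of COL 1, COL 2, AB 1, AB 2 and AB 3 (limma adjusted p up to 0.124), that of AT1G33790 without COL 1 or AB 3 (up to 0.0691) and that of AT4G07820 without COL 2 or AB 1 (up to 0.0599). The call of AT1G11850 also ended with quantile normalization (0.0735) and median centring (0.0526). In the fit to AB and COL alone, with fewer arrays, 0 probe sets were called, so the call of SPF1 ended too.

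SIZ1 and COL were compared to find the transcripts that change with the loss of the ligase. In SIZ1, 438 probe sets were higher and 294 lower (limma, adjusted p under 0.05), and 370 of the 732 name 1 gene. A further 343 are unnamed here, so the genes below have the largest changes among the named ones only. AT3G16530, a legume-type lectin, rose by 3.59 (12.0-fold), from 5.15 ± 1.01 (SD, n = 3) to 8.74 ± 0.26 (limma adjusted p = 0.00509). AT5G03350, a further legume-type lectin, rose by 2.03, from 2.33 ± 0.06 to 4.36 ± 0.97. AT3G04210, which encodes a TIR-NBS protein of the kind used as immune receptors, rose by 2.19, and AT1G72800 by 2.93 (limma adjusted p = 3.13e-05 and 0.000433). AT2G19970, a PR-1-like protein, rose by 2.07, and AT2G22880, with a VQ motif, by 2.17. AT1G27030 (2.23, SE 0.18) and AT2G18210 (4.28-fold) complete the 8 named by the rule for rises.

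Among the falls in SIZ1, AT1G62510, a protein of the lipid-transfer type, fell from 8.60 ± 0.13 (SD, n = 3) to 6.50 ± 0.54 (limma adjusted p = 0.00194). The antimicrobial thionin THI2.2 fell by 1.71, from 6.70 ± 0.29 to 4.99 ± 0.07 (limma adjusted p = 0.00412). AT5G22580, a stress-responsive A/B barrel protein, fell by 1.93 (SE 0.29) and AT1G70880, of the Bet v 1 family, changed by -1.62 (SE 0.15). ZW9 (-1.55), AT1G14120, an oxygenase of the 2-oxoglutarate type (-1.36), and AT5G52070 (-1.29) followed. None of the 16 genes with the largest changes was called between AB and COL; THI2.2 stood at 7.89 ± 0.32 in AB, above COL.

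**Figure D2:**
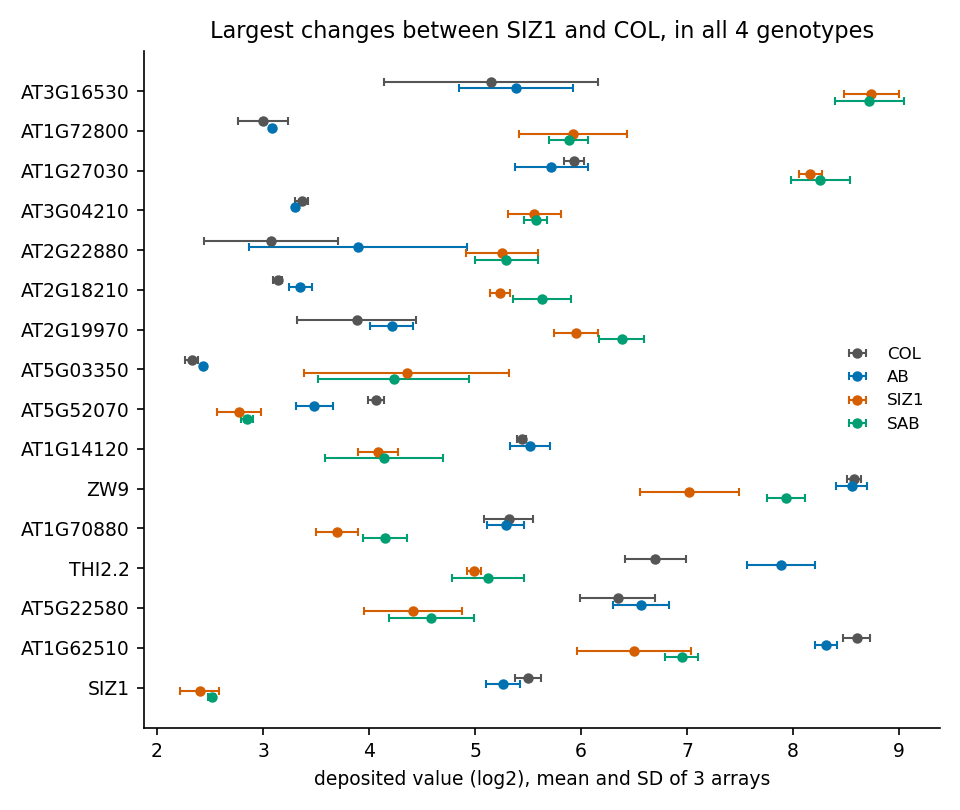
Deposited log2 values (x axis, mean and SD of 3 arrays) of the 8 genes with the largest rise and the 8 with the largest fall between SIZ1 and COL (y axis), in the 4 genotypes. SIZ1 and SAB lie together, for example at 8.74 and 8.72 for AT3G16530, where COL lies at 5.15 and AB at 5.39.

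The photosynthesis list was lower in SIZ1 (camera adjusted p = 0.00880, and adjusted p = 0.371 with an estimated correlation). LHCB4.2 (-0.84, SE 0.15) and LHCB4.1 (-0.19, SE 0.04), which encode light-harvesting proteins of photosystem II, fell, and the other 4 members were not called. Adjusted over the list alone, 3 of the 6 were lower. With quantile normalization the change of LHCB4.1 was -0.08 and its call ended (limma adjusted p = 0.312), as did those of AT2G22880 (0.0561) and AT5G03350 (0.0571). The call of the list ended with quantile normalization (camera adjusted p = 0.110) and without SIZ1 3 (0.0866). GI, a clock gene and the only measured member of the circadian list, fell by 0.95 (SE 0.17, limma adjusted p = 0.0176). GAPC2, a glycolytic enzyme in the list of reference genes, rose by 0.54 (SE 0.05, limma adjusted p = 0.00142), while the 3 other reference genes differed by -0.09 to 0.04 and were not called. The SUMO pathway list had a camera adjusted p of 0.0513, with SIZ1 as its only called member and 2 lower when adjusted over the list alone. It was called with the brighter probe sets alone (0.0178) and without COL 1 (0.0148), SIZ1 1 (0.0108) or AB 2 (0.0129). In the salicylic acid list, SAG101, WRKY53 and GRX480, its only members with a named probe set, differed by 0.21, 0.12 and 0.04. None was called, over all probe sets or adjusted over the list alone. It and the 7 other tested lists had camera adjusted p from 0.179 to 0.959. For the cold and flavonoid lists median and mean differed in sign. Of the lists too small to test, the glucosinolate list had 2 members higher when adjusted over the list alone. No member of the jasmonate, cell cycle, senescence, iron, sugar and brassinosteroid lists was called, but each had only 1 or 2 measured loci. The phosphate, abscisic acid, nitrate, DNA damage and seed lists had 0 under a name, and their loci may be among the unnamed probe sets. The absence of calls in these lists therefore says little about their pathways.

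The 69 measured loci of the plastid genome, a list added after the data were seen, had a median change of -0.30 in SIZ1. Of these, 7 were lower and 0 higher, among them ndhK (from 6.59 to 5.59), ndhJ (-0.96, SE 0.20) and psbB (-0.80, SE 0.14), and 28 were lower when adjusted over the list alone. With median centring 12 were lower over all probe sets. Its camera adjusted p was 5.45e-13, and adjusted p = 0.461 with an estimated correlation. The poly-A controls also lay lower in SIZ1 (-0.42 on average relative to COL). With the replicate number as a block 607 probe sets were higher and 560 lower, 1167 in all, and 672 of the 732 were among them. The count was 340 without COL 1, 401 without SIZ1 1 and 317 without SIZ1 2; the call of AT2G22880 ended without any 1 of the 6 arrays (limma adjusted p up to 0.151), and that of AT1G14120 without COL 1 or SIZ1 2 (up to 0.0650). Calls also ended for AT5G03350 without COL 1, COL 2, COL 3, SIZ1 1 or SIZ1 2 (up to 0.130), for GI and LHCB4.2 without COL 1, COL 2, SIZ1 1 or SIZ1 2 (up to 0.0693 and 0.0631), and for LHCB4.1 without those or SIZ1 3 (up to 0.0978).

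SAB and COL were compared in the same way. In SAB, 377 probe sets were higher and 354 lower (limma, adjusted p under 0.05), and 373 of the 731 name 1 gene. The genes with the largest changes were mostly those named for SIZ1. AT3G16530 rose by 3.57 to 8.72 ± 0.32 (SD, n = 3), AT1G72800 by 2.89 to 5.88 ± 0.18, AT2G19970 by 2.50 to 6.38 ± 0.21 and AT2G18210 by 2.49 to 5.63 ± 0.27 (limma adjusted p = 0.00547, 0.000539, 0.00176 and 2.35e-05). AT1G27030 rose by 2.32 and AT2G22880 by 2.22. The list also held AT1G19960 (2.40) and AT2G37870, a protein of the lipid-transfer type (2.27). Among the falls, AT5G22580 fell by 1.76, AT1G62510 fell by 1.65 and THI2.2 fell by 1.58, next to SIZ1 and SPF1.

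Plastid-encoded transcripts took 3 of the 8 places among the largest falls in SAB. The photosystem II gene psbC fell by 1.96, from 10.44 ± 0.05 (SD, n = 3) to 8.49 ± 0.44 (limma adjusted p = 0.00559), psbN fell by 1.81 and petL, of the cytochrome b6f complex, fell by 1.58. Of the 69 plastid loci, 21 were lower and 0 higher, with a median change of -0.33, and adjusted over the list alone 35 were lower and 1 higher. Its camera adjusted p was 2.47e-15, and adjusted p = 0.467 with an estimated correlation. The poly-A controls averaged -0.18 in SAB relative to COL. In the fixed lists, the SUMO pathway (camera adjusted p = 0.00233, and adjusted p = 0.0545 with an estimated correlation) and photosynthesis (camera adjusted p = 0.0120, and adjusted p = 0.470 with an estimated correlation) were lower. The first rests on SIZ1 and SPF1, its called members: its median was -0.05, the other 4 members changed by -0.09 to 0.04, and the list was not tested without SIZ1 and SPF1. The called member of the second was LHCB4.2 (-0.85, SE 0.15), and 2 members of that list were lower when adjusted over the list alone. The photosynthesis call ended with quantile normalization (camera adjusted p = 0.0928), with the brighter probe sets alone (0.138) and without SAB 3 (0.267), and the root markers were called without SIZ1 3 (0.0243). GI fell by 1.08 (SE 0.17), GAPC2 rose by 0.41 (SE 0.05), and UGT78D2, a flavonoid glucosyltransferase, rose by 0.64 (SE 0.12). The 8 remaining tested lists had camera adjusted p from 0.102 to 0.912, and median, mean or test differed in sign for the salicylic acid, flowering time and reference lists. With the replicate number as a block 545 probe sets were higher and 628 lower, 1173 in all, and 663 of the 731 were among them. The count was 334 without COL 1, 413 without SAB 1, 458 without SAB 2 and 375 without SAB 3; the call of AT2G22880 ended without any 1 of the 6 arrays (limma adjusted p up to 0.143) and that of AT5G22580 without SAB 3 (0.0502). Calls also ended for AT1G19960 without COL 1, COL 2, COL 3, SAB 1 or SAB 2 (up to 0.122), for petL and UGT78D2 without COL 1, COL 2, COL 3, SAB 1 or SAB 3 (up to 0.130 and 0.0855), and for LHCB4.2 without COL 1, COL 2, SAB 1 or SAB 3 (up to 0.0658). With quantile normalization those of AT2G22880 (0.0501) and petL (0.0557) ended.

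**Figure D3:**
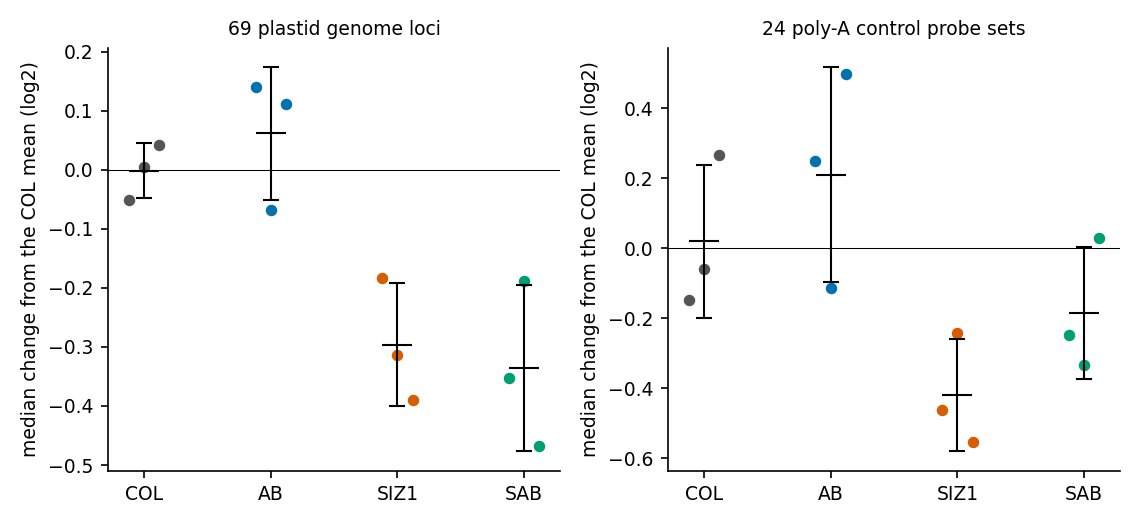
Median change from the COL mean (y axis, log2) of the 69 plastid genome loci and of the 24 poly-A control probe sets in each of the 12 arrays, by genotype (x axis). Points are arrays and bars are the mean and SD of 3; for the plastid loci all SIZ1 and SAB arrays lie at -0.18 or lower and all COL and AB arrays at -0.07 or higher.

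The changes of SIZ1 and SAB were compared across probe sets. Of the calls, 294 were higher in both and 193 lower in both, and none went in opposite directions. Independent lists of these sizes would share 7.26 and 4.58. Both comparisons use the same COL arrays, and 100 simulations of unchanged groups against them gave 0.01 shared calls on average and at most 1. The simulations hold no effects and the 3 COL arrays are too few to be split, so part of the excess may come from the shared controls. The changes correlated at r = 0.883 (Spearman's rho 0.722) across probe sets, which are not independent replicates, against r = 0.497 in the simulations. The covariance was 0.0531 against a simulated 0.00773. AB and SAB shared 4 calls, and AB and SIZ1 shared 3, all lower in both, and 22 and 21 with the replicate number as a block. The covariance of AB with SAB was 0.00883, above the simulated mean of 0.00775 and the highest of the 100 simulations, 0.00857. That of AB with SIZ1 was 0.00723, below the simulated mean of 0.00777. The simulations left out the effect of the replicate number, which the pairing cancels in the real differences, so their covariances may be too high. The covariances of AB therefore do not settle whether it shares changes with SAB or SIZ1. Lower than COL in all 3 lines were 3 probe sets that are unnamed here, the strongest by -1.51 in AB, -1.38 in SIZ1 and -1.36 in SAB. With the replicate number as a block SIZ1 and SAB shared 797 calls. Without COL 1 they shared 225, without SIZ1 1 310, without SIZ1 2 244, without SAB 1 307, without SAB 2 299 and without SAB 3 281.

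**Figure D4:**
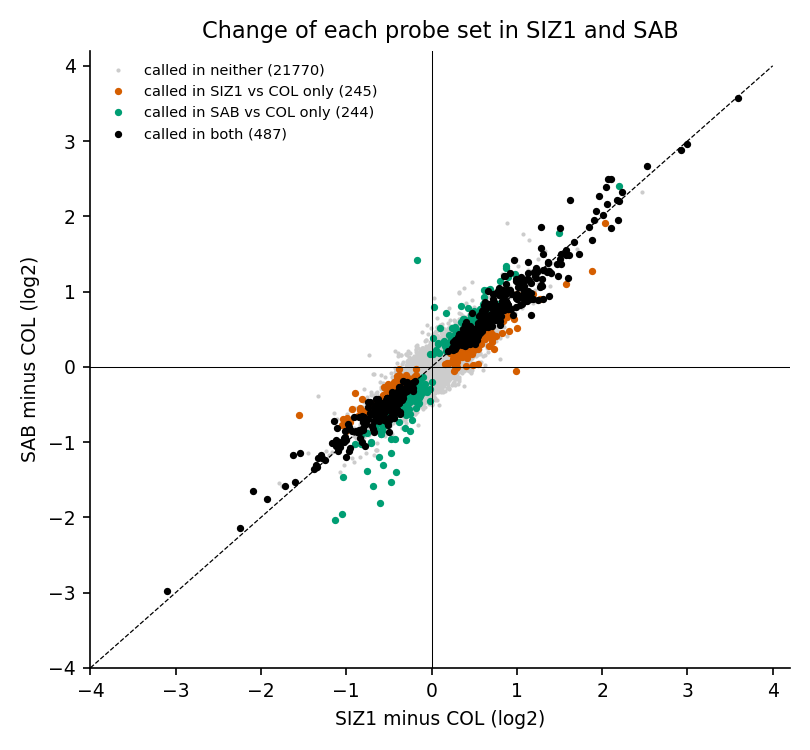
Change of each of the 22746 probe sets between SIZ1 and COL (x axis, log2) and between SAB and COL (y axis, log2), coloured by the comparisons in which limma called it. The 487 probe sets called in both lie near the diagonal (dashed), with none in the quadrants of opposite direction.

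SAB and SIZ1 were compared to see what differs between the lines in which the SIZ1 signal was low. No probe set was called (limma, lowest adjusted p = 0.150), and 981 of 22746, 4.31%, had an unadjusted p under 0.05. SPF1 was lower in SAB by 1.05 (SE 0.13) and was among the lowest p-values without passing the threshold (limma adjusted p = 0.150). QQS, a gene known only from Arabidopsis thaliana, had a difference of 1.59 (SE 0.24) that was not called, and psbC stood at 9.39 ± 0.49 (SD, n = 3) in SIZ1 and 8.49 ± 0.44 in SAB. None of the 10 tested lists was called (camera adjusted p from 0.304 to 0.562), except the SUMO pathway with the brighter probe sets alone (0.0275 against 0.304), and mean and median of the SUMO and auxin lists differed in sign. The difference between SAB and SIZ1 correlated with that between AB and COL at r = 0.0816 (rho 0.0527) across probe sets, where no array is shared. Of the 14 probe sets called between AB and COL, 7 had the same sign between SAB and SIZ1. On simulated data for this comparison 88.1% of probe sets changed by 1 and 35.8% of those changed by 0.5 were called, so small differences would often be missed. Those data held 200 changed probe sets. With fewer the threshold is stricter, so differences near 1, such as that of SPF1, can be missed too. The count was 5 without SAB 2, and 2 without SAB 3, SIZ1 1 or SIZ1 2.

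SAB and AB were compared to see what differs between the lines in which SPF1 was low. In SAB, 534 probe sets were higher and 473 lower (limma, adjusted p under 0.05). The largest rises were those of AT3G16530 (3.33, SE 0.46), AT1G72800 (2.80, SE 0.22), AT1G27030 (2.54, SE 0.18) and AT2G18210 (2.28, SE 0.12). M17, a late embryogenesis abundant protein, was lower by 2.90, at 5.99 ± 0.99 (SD, n = 3) in AB and 3.08 ± 0.60 in SAB (limma adjusted p = 0.0158). THI2.2 was lower by 2.76, SIZ1 was lower by 2.75 and AT2G28490, a seed storage protein of the cupin family, was lower by 2.17. M17 and AT2G28490 stood at 3.18 ± 0.74 and 2.93 ± 0.75 in COL, so they were highest in AB. BCAT4, an enzyme of glucosinolate synthesis, was higher in SAB by 1.83 (SE 0.30, limma adjusted p = 0.0107). HSP17.6B (-0.61), GI (-0.84) and the cold-induced dehydrin COR47 (-0.39) were lower, and GAPC2 (0.37) was higher. No fixed list was called (camera adjusted p from 0.0881 to 0.756), and mean and median of the SUMO, cold and reference lists differed in sign. The heat shock list was called without COL 2 (0.0406) or AB 3 (0.0338), and photosynthesis without AB 3 (0.0251). Of the 69 plastid loci 23 were lower (camera adjusted p = 3.18e-22, and adjusted p = 0.430 with an estimated correlation), where the poly-A controls averaged -0.18 in SAB and 0.21 in AB relative to COL.

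The difference between SAB and AB correlated with that between SIZ1 and COL at r = 0.709 (rho 0.493) across probe sets, with no array shared. Among the 732 probe sets called between SIZ1 and COL, 698 had the same sign between SAB and AB, and the slope through the origin was 0.830. With the replicate number as a block the comparison of SAB and AB called 1552 probe sets, 773 higher and 779 lower. Their number was 598 without SAB 1, 655 without SAB 2, 580 without AB 1 and 469 without AB 2; the calls of COR47 and GI ended without any of SAB 1, SAB 2, SAB 3, AB 1 and AB 2 (limma adjusted p up to 0.151 and 0.0962), and that of M17 without SAB 1 or SAB 3 (up to 0.0580). With quantile normalization that of COR47 ended (0.0532).

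Whether the change in SAB equals the sum of the changes in SIZ1 and AB was tested last. No probe set departed from the sum (limma, lowest adjusted p = 0.0555), and 1218 had an unadjusted p under 0.05. AT3G55640 (-0.71, SE 0.08) and 3 probe sets that are unnamed here (1.53, 1.88 and -1.05) shared that adjusted p. The last 3 were called between AB and COL, and the one with 1.88 stood at 7.16 in COL, 5.56 in AB, 7.38 in SIZ1 and 7.65 in SAB. The one with 1.53 stood at 4.82 in COL and at 3.31, 3.44 and 3.46 in AB, SIZ1 and SAB, so all 3 lines lay below COL. The heat shock list lay below the sum (camera adjusted p = 0.0429, and adjusted p = 0.199 with an estimated correlation), with a median of -0.35, none of 4 members called and 2 lower when adjusted over the list alone. That call ended with the replicate number as a block (0.0518) and without SIZ1 3 (0.224), SAB 1 (0.0966) or SAB 2 (0.101). The other tested lists had camera adjusted p from 0.0772 to 0.717, photosynthesis was called with the block (0.0379), and the test of the root markers differed in sign from their median. Of these lists, SUMO was called without COL 1, AB 2 or SIZ1 1 (0.0480, 0.0409 and 0.0361), salicylic acid without AB 1 or SIZ1 1 (0.0329 and 0.0361), photosynthesis without AB 1, SIZ1 1 or SAB 3 (0.0329, 0.0361 and 0.0177) and reference genes without AB 3 or SIZ1 1 (0.0289 and 0.0429). The plastid genome had a median of -0.14 (camera adjusted p = 0.00176, and adjusted p = 0.892 with an estimated correlation). With the replicate number as a block 12 probe sets were called, 5 above and 7 below the sum, among them AT1G33790 (-1.10) and AT1G52100 (-1.22). On simulated data for this test 62.7% of probe sets that departed by 1 and 29.9% of those that departed by 0.5 were called. The count was 3 without COL 3, and 1 without AB 1 or SAB 2.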

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

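All tests of explanations in this part were chosen after the pattern they bear on was seen, except that on RNA degradation and those on other splits of the arrays, which were written down before their values were computed.

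The hybridization control probe sets, which detect labelled RNA added just before hybridization and take no part in the comparisons, stood above their COL level on SAB 3 (median difference 0.95) and on AB 3 (0.37), where the highest COL array lay at 0.28. On SIZ1 3 they stood at -1.16. Without SAB 3 and SIZ1 3 the number of calls between AB and COL was 8.

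The changes between AB and COL were not seen between SAB and SIZ1: the 50 brighter probe sets with the lowest p between AB and COL, SPF1 left out, were chosen on 2 replicate numbers and read in the arrays of the other. The median change in the direction of selection was 0.36 between AB and COL (0.34 to 0.38 over the 3 choices, which overlap in their arrays and are not independent) and -0.015 between SAB and SIZ1, a difference of 0.37 that argues against selection on noise, and in the test of single probe sets against the sum limma called 0 (lowest adjusted p = 0.0555, with 1218 at an unadjusted p under 0.05) and 12 with the replicate number as a block. A difference of COL from every mutant would move SIZ1 against COL as well, where the median was 0.027. That bears on the 50 as a set, since 3 of the 14 probe sets called in AB were lower in SIZ1 and SAB too. The strongest of these is also among the 12 called with the block. A different age of AB 1 and AB 2 alone, which their labels leave possible, would leave AB 3 unmoved. Probe sets chosen on replicates 1 and 2 moved by 0.34 there, a value that rests on 1 pair of arrays, AB 3 and COL 3. A condition shared by the 3 AB samples and no others remains open, as does the biological explanation, that the changes in AB may need the function lost in SIZ1.

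The 2 SIZ1 probe sets moved in opposite directions in SIZ1 and SAB. A wider activation of the region around the insertion would raise its neighbours. The 13 other measured loci within 50 kb had a median change of -0.010 in SIZ1 (highest 0.19) and 0.0074 in SAB (highest 0.35), but 11 of them lay near the floor in COL, so this stays open. A partial transcript beyond the insertion may raise 1 probe set while the other falls, and the rise of 0.90 in SAB is what it needs, but the positions of the probes and of the insertion, not used here, keep it open. The gene table lists a former separate locus as a synonym of SIZ1, so the probe sets may report different parts of what is now 1 gene.

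Plastid-encoded transcripts were lower in SIZ1 and SAB. The 6 arrays of SIZ1 and SAB had lower plastid medians than the 6 of COL and AB (exact permutation test, two-sided, p = 0.00216, n = 6). This grouping was chosen after seeing the values and the test ignores the replicate numbers, so that p is no independent support. SIZ1 and SAB, each against COL, gave p = 0.1 (exact permutation test, two-sided), the smallest that 3 arrays against 3 allow. Without SAB 3 and SIZ1 3 the highest of the remaining 4 medians was -0.18, below the lowest of COL and AB, which argues against those arrays as the cause. More degraded RNA would raise the signal of the 3' over the 5' end of the housekeeping controls, which differed by -0.033 in SIZ1 and SAB (exact permutation test, two-sided, p = 0.329), with SIZ1 and SAB on opposite sides of COL. The labelling cannot be told apart: the poly-A controls differed by -0.42 in SIZ1 and SAB (exact permutation test, two-sided, p = 0.0130), and the slope within genotypes predicted a share of 0.0985 of the plastid shift, with a 95% interval from -0.404 to 0.601, so a true fall of plastid transcripts and lower labelling both stay open.

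Other splits of the arrays bear on whether chance groupings give as many calls. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. Splits that mix genotypes also add the differences between them to the spread, which lowers their counts. For AB against COL the real split called 14 and 1 of 10 splits, the real one, called as many, with 1 in the highest other split. For SIZ1 against COL the real split called 732, with 1 of 10 splits as large and 1 in the highest other. For SAB against COL these were 731, 1 and 2, and for SAB against AB 1007, 1 and 0. For SAB against SIZ1 all 10 splits called 0, and with a real count of 0 no split can have fewer. The 3 other splits that part all 3 pairs of replicate numbers called 0 in each of these comparisons, and each of the 6 remaining splits parts 1 pair. For the departure from the sum the real count was also 0, so that all 100 splits had as many calls was fixed in advance and decides nothing. The highest other had 9.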

How the results depend on the processing

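The fit without SAB 3 and SIZ1 3, and the overlap of calls under left-out arrays and the block, were added after the data were seen; the other alternatives were fixed before. Where no cause is given, the cause was not tested.

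The replicate block called 74 probe sets in AB, 1167 in SIZ1 and 1173 in SAB against COL, 1552 between SAB and AB and 12 that departed from the sum, with 797 shared by SIZ1 and SAB, and 1 list in AB. Array quality weights gave 68, 1491 and 3953 against COL, 2454 between SAB and SIZ1, 5803 between SAB and AB and 71 departures; their estimation stopped before it converged and gave SAB 2 a weight of 33.3, the next highest being 2.47, so these counts rest largely on 1 array. With the brighter probe sets alone the counts were 43 for AB, 4 for SAB against SIZ1 and 3 departures. With the probe sets that name 1 gene, which are fewer, they were 4 (AB), 336 (SIZ1), 324 (SAB) and 483 (SAB against AB). Fits to only the groups compared, with fewer arrays, gave 0 for AB, 131 for SIZ1 and 230 for SAB. Of the named calls, 5 ended in AB, SPF1 among them, 11 in SIZ1, 9 in SAB and 3 between SAB and AB. In SIZ1 1 was gained. The 2-fold threshold, which is stricter by construction, left 6, 121 and 130 against COL and 175 between SAB and AB. Departures numbered 2 with median centring and 2 with the trend and robust moderation. Without SAB 3 and SIZ1 3 AB had 8.

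The number of called lists moved from 2 in AB, 1 in SIZ1 and 2 in SAB to 1, 0 and 0 with an estimated correlation, to 1, 2 and 1 with the brighter probe sets, to 0 in SIZ1 and 1 in SAB with quantile normalization and without SAB 3 and SIZ1 3 (AB had 3 in the latter), and to 1 in SAB with all probe sets of each locus. Over only the called probe sets, the correlation of SAB minus SIZ1 with AB minus COL was 0.227 and that of SAB minus AB with SIZ1 minus COL 0.920.

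With each array left out in turn, the counts ran from 7 to 27 for AB, 317 to 909 for SIZ1, 334 to 682 for SAB, 0 to 5 for SAB against SIZ1, 469 to 819 for SAB against AB and 0 to 3 for the departures. Called lists ran from 1 to 4 in AB, 0 to 2 in SIZ1 and 1 to 3 in SAB, shared calls from 225 to 554, and the correlations from 0.0123 to 0.132 and from 0.652 to 0.709.

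The named genes formed 70 pairs of a gene and a comparison, of which 61 were called in the main fit. Of these 61 called pairs, 30 lost the call under some alternative. The 1040 recomputed values include those of uncalled pairs. Of these 1040, 898 kept their direction and side of the threshold, 130 lost the call, 3 gained one and 9 changed sign. All 9 were ULP1B, which lies near the floor and was called in none: in SAB -0.0046 with quantile normalization, -0.016 with array weights, -0.028 without SAB 3 and SIZ1 3 and -0.028 to 0.032 with single arrays left out; in AB 0.015 with median centring and -0.016 to 0.0054 with single arrays left out. Signal near the floor limits what can be read of dim transcripts such as SPF2.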

Other observations

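The tests in this part were chosen after the data were seen.

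Of 47 measured UDP-glycosyltransferases (UGT), which attach sugars to small molecules, 5 were higher and 1 lower in SIZ1 (limma, adjusted p under 0.05). UGT76B1, which glucosylates immune regulators, rose by 1.29 (SE 0.17), UGT73B5 by 1.29 (SE 0.18) and UGT73B4 by 1.15 (SE 0.13), while UGT72E1, which acts on lignin precursors, fell by 0.66 (SE 0.12). In SAB 5 were higher and 1 lower, and the first 3 of these genes rose by 1.08, 1.09 and 0.90. The camera adjusted p of the family was 0.000305 in SIZ1 and 0.000702 in SAB, with adjusted p = 0.461 and 0.467 with an estimated correlation. With quantile normalization 4 were higher and 1 lower in each line, and with median centring 4 and 1 in SAB. The sugar transporter SWEET2 rose by 1.35 in SIZ1 and 1.26 in SAB, and SWEET11 fell by 0.43 and 0.59, while the 12 other measured members of their family were not called in either line (camera adjusted p = 0.970 and 0.879). BGLU45, a glucosidase of lignin precursors, rose by 1.14 and 1.15. The cell wall genes XTH20 (1.48 in SIZ1 and 1.21 in SAB) and EXPA4 (0.78 and 0.76) rose. UBC20, a ubiquitin-conjugating enzyme, rose by 0.71 and 0.82, and ATG8F of the autophagy pathway fell by 0.40 and 0.36. All of these were called in both lines as deposited, and the call of ATG8F in SAB ended with median centring, and each was chosen after its value was seen.

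M17 and AT2G28490, both seed-type transcripts, had their highest means in AB, but their differences from COL (2.80 and 1.69) were not called (limma adjusted p = 0.104 and 0.151). A hypothesis is that seed reserve transcripts as a group may persist in AB seedlings. It was tested on 17 other seed loci, of which 14 were higher in AB than in COL, with a median difference of 0.12. None was called, 2 were higher adjusted over the list alone, and PAP85 stood at 3.41 in AB and 2.26 in COL. The camera adjusted p was 0.000117, and adjusted p = 0.804 with an estimated correlation, so the test leaves the hypothesis open. Between SAB and AB 2 of the 17, AT3G17520 (-1.12) and AT2G25890 (-0.69), were lower (camera adjusted p of the list 0.00189, and adjusted p = 0.430 with an estimated correlation). For the departure from the sum its camera adjusted p was 0.0422, with adjusted p = 0.107 with the replicate number as a block and adjusted p = 0.892 with an estimated correlation. In SIZ1 and SAB against COL none of the 17 was called (camera adjusted p = 0.334 and 0.619).

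Of the 30 added lists, camera called 2 in AB (plastid and seed), 3 in SIZ1 (plastid, UGT and the autophagy family ATG, with adjusted p = 0.0439 for the last, and 0.0956 with the replicate number as a block) and 2 in SAB (plastid and UGT), and 0 with an estimated correlation.

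The plastid medians were -0.30 in SIZ1 and -0.33 in SAB. Without SAB 3 and SIZ1 3 they were -0.25 and -0.25, with 8 and 12 loci called lower.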
